A study of Mus musculus with 12 samples.

How the data were processed

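Mouse RNA was measured on expression arrays whose probe set names and control probe sets match the mouse platform of the probe table used. There were 12 arrays in 4 groups of 3, kidney RNA at 10 ng and universal reference RNA at 10, 3 and 0.3 ng, with groups, inputs and replicate numbers taken from the sample titles. The deposited values are linear intensities, 1 per probe set and array, and were found from the values themselves to be scaled so that the 2% trimmed mean of each array is 500. The quantiles differ between arrays, so no quantile normalization was applied. How the authors summarised probes to probe sets, the background correction, the software, the amplification and labelling, and the origin of the replicates are not given in the sources used here. The meaning of the code pRS in the titles is not given either.

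The values were used as deposited, because the trimmed means already agreed, and log2 values were taken after adding a pseudocount of 3.9, the 10th percentile of all positive values. Of 45101 probe sets, 64 control probe sets were left out of the tests. A probe set was tested when the highest of its 4 group means lay above the 40th percentile of that quantity (a signal of 65.4), which kept 27022. Of all probe sets, 34945 carried 1 gene symbol, 932 several and 9160 none, for 18193 different genes, and 12820 genes had a tested representative. Symbols were looked up by gene ID for 34741 probe sets in the RefSeq gene table of GRCm38.p6, and 0 changed. A gene was represented by the probe set naming it alone with the highest mean log2 value over all arrays. The background level, 33.65, was the 95th percentile of 27 Bacillus control probe sets over all arrays. Where every array of the dimmer group lay below it, a fold is given as a lower bound against that level.

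Each comparison was fitted by limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the 3 arrays of each of its 2 groups, with no covariates. Other groups were left out of a fit, since the spread may change with input. Each fit still takes the same variance for both of its groups. The median SD of log2 values was 0.69 in the reference at 0.3 ng and 0.24 at 10 ng. Tests with the 0.3 ng arrays therefore rest on an assumption of equal spread that the data do not meet. Adjusted p-values are Benjamini-Hochberg values over the 27022 probe sets, with a threshold of 0.05, and all tests are two-sided. The comparisons were kidney against the reference at each input, and the reference inputs against each other, with a limma F-test over the 9 reference arrays. The kidney comparisons at unequal input change tissue and input together. A gene list was tested by limma's camera with a preset correlation of 0.01 and with an estimated correlation, which compares the list with the other genes, and by fry, whose p asks whether its genes move on balance 1 way. P-values of camera were adjusted over the 22 lists of a comparison. List medians are also given with signals under background raised to it (the bound), and so are the log2 fold changes of named genes of which the mean of the dimmer group, but not every array, lay under background. Of the lists, 7 of 34 histone symbols and 44 of 75 ribosomal protein symbols had a probe set of their own, so those lists are partial.

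Genes were named by a rule. For kidney against the reference at 10 ng, they were the 12 genes with the largest fold change in each direction among those called in which every array of 1 group lay above every array of the other. For the input comparisons they were the 8 in each direction, or all that passed. In each list they were up to 4 called members with the largest change, or 2 members of a list with no call. For the input comparisons the uncalled list members are not all printed, and a few examples stand for them. Comparisons, tests, lists, naming rule and alternatives were set before the data were examined, except where the text says otherwise.

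Replicate spread was the SD of log2 values among the 3 arrays of a group, with Pearson's correlation of pairs of arrays across probe sets. Ratios of 3′ to 5′ control probe sets, and control signals, were compared by two-sided exact permutation tests, which cannot go below p = 0.1 with 3 against 3 arrays. Agreement of fold changes was set beside 20 simulations of unchanged groups that share arrays. The fits were tested on simulated data with 100 probe sets changed 2-fold and 100 changed 4-fold among 27022. For kidney against the reference at 10 ng, 39% of those with a 4-fold change and 1% with a 2-fold change were called, with 3 unchanged probe sets called. With so few changes the adjusted threshold is stricter than in the real kidney comparison, where 60.1% were called. These shares therefore do not give the power of that comparison. In every simulation a probe set took the mean spread of others of like signal, and none changed more than 4-fold. For the input comparisons, too, the shares do not give the power for larger changes or for probe sets of smaller spread. Tables and figures also used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

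Alternatives were quantile normalization, centring of each array on its median, a pseudocount 10 times smaller or 4 times larger, no filter, a filter on the mean over all arrays (above its 60th percentile), all arrays in 1 fit, an intensity trend in eBayes, array weights, the replicate number as a block, at least a 2-fold change, the mean of a gene's probe sets, and leaving out each array in turn. A floor at background and further gene families were added after seeing the data. No array was left out, and no pair among the 66 was identical (0 found).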

Results

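The series title says that ways of amplifying RNA from nanogram inputs were compared, and each sample title carries the code pRS, whose meaning the labels do not give. RNA was measured on 12 arrays in 4 groups of 3. Kidney RNA from a commercial supplier (Ambion) was assayed at 10 ng. A universal mouse reference RNA (spelt Strategene in the labels), a commercial pool made from cell lines, was assayed at 10, 3 and 0.3 ng. Every array carried 45101 probe sets and had the same 2% trimmed mean of 500, so signals are in units of that scale. The median signal of an array was 58.4 ± 1.57 for kidney, 69.8 ± 1.71 for the reference at 10 ng, 75.1 ± 4.39 at 3 ng and 50.8 ± 2.95 at 0.3 ng (mean ± SD, n = 3 arrays each). Signals below 33.65, the level set by the Bacillus control probe sets, made up 39.0% ± 0.887, 35.7% ± 0.529, 34.1% ± 1.31 and 41.2% ± 1.03 of the probe sets in the same order. The number of arrays limits the precision. The labels do not say whether replicates came from separate animals, cultures or amplifications, so all p-values measure only the spread between these arrays.

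Markers of the renal tubule, from the proximal tubule to the collecting duct, were higher in kidney RNA than in reference RNA at 10 ng, the comparison that sets a tissue against a pool of RNA. All 43 measured proximal tubule genes rose, with a median log2 fold change of 7.62 (6.34 with signals under background raised to it; camera adjusted p = 6.6e-22). Slc27a2, a fatty acid transporter, measured 11719 ± 182 in kidney and 11.7 ± 11.1 in reference RNA (SD, n = 3), at least 348-fold higher. Slc13a1, the sodium sulfate cotransporter, measured 7732 ± 262 in kidney and was at least 230-fold higher, and Slc5a8, a monocarboxylate transporter, was at least 239-fold higher. Cyp4b1, a cytochrome P450, was at least 243-fold higher.

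All 19 genes of the loop of Henle and distal tubule rose, with a median log2 fold change of 5.57 (5.15 at the background bound; camera adjusted p = 2.9e-10). Umod, which encodes uromodulin of the thick ascending limb, measured 10850 ± 53.4 in kidney and was at least 322-fold higher than in reference RNA. The potassium channel gene Kcnj16 was at least 298-fold, the sodium-potassium-chloride cotransporter gene Slc12a1 at least 194-fold and Calb1, which encodes a calcium-binding protein, at least 163-fold higher. All 20 measured collecting duct genes rose as well, with a median of 4.04 (3.21 at the bound; camera adjusted p = 6.39e-10). Among them, the urea transporter gene Slc14a2 was at least 95-fold and the water channel gene Aqp4 at least 120-fold higher. Fxyd4 measured 4424 ± 91.5 against 28.2 ± 12.6 (log2 fold change 6.78 at the bound), and Car2, carbonic anhydrase of the intercalated cells, measured 5782 ± 269 against 60.7 ± 22.6 (6.54).

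Podocyte genes went both ways. Of 9 measured, 5 rose and 3 fell, with a median log2 fold change of 2.65 that camera did not call (adjusted p = 0.122). Dach1 measured 3008 ± 174 in kidney against 34.2 ± 11.8, Clic5 2484 ± 215 against 233 ± 16.3, and Podxl, the podocalyxin of the foot process surface, 3120 ± 23.5 against 341 ± 48.2 (log2 fold changes 6.35, 3.39 and 3.19; n = 3). Tcf21 was at least 18.5-fold higher. The genes that fell were Kirrel (−2.75), Foxc2 (−1.22) and Wt1 (−0.69), chosen for mention after their values were seen. All 18 endothelial genes rose, with a median of 3.10 (1.90 at the bound; camera adjusted p = 4.48e-07). Emcn was at least 47.3-fold higher, Robo4 at least 6.57-fold higher, and the angiopoietin receptor gene Tek measured 3356 ± 389 against 67.6 ± 87.5 (6.31). Ptprb, an endothelial phosphatase gene, measured 1733 ± 49.5 against 50.1 ± 1.87 (5.01).

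Metabolic genes of the kidney rose together. Of 25 measured genes for amino acid breakdown and gluconeogenesis, 24 rose and 0 fell, with a median log2 fold change of 5.20 (4.56 at the bound; camera adjusted p = 8.47e-13). Hao2 was at least 306-fold higher, as was Fbp1, the fructose bisphosphatase of gluconeogenesis, which measured 10309 ± 384 against 13.6 ± 14.6. Hgd, of tyrosine breakdown, was at least 218-fold and Dao, D-amino acid oxidase, at least 117-fold higher. Of 24 genes of fatty acid oxidation and the peroxisome, 23 rose and 0 fell (median 1.85; camera adjusted p = 9.49e-11). Ehhadh measured 4509 ± 240 against 30.4 ± 5.47 (6.90 at the bound), Decr1 3288 ± 176 against 287 ± 56.8 (3.52) and Acadm, the medium-chain acyl-CoA dehydrogenase, 7626 ± 58.6 against 801 ± 110 (3.25). Ppara, their transcription factor, was at least 22.3-fold higher.

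All 11 genes of the renin-angiotensin system and kidney hormones rose, with a median log2 fold change of 4.22 (4.09 at the bound; camera adjusted p = 7.4e-07). Enpep, an angiotensin-cleaving peptidase, measured 3507 ± 308 against 22.5 ± 20.1 (6.41 at the bound). Mme was at least 48.4-fold, the vitamin D hydroxylase gene Cyp24a1 at least 31.9-fold and Agt, which encodes angiotensinogen, at least 19.7-fold higher. Of 61 oxidative phosphorylation genes, 41 rose and 1 fell, with a smaller median of 0.51 (camera adjusted p = 8.73e-08). That call was lost with adjusted p = 0.206 with an estimated correlation. Uqcrfs1 measured 3490 ± 87.4 against 1030 ± 55.4 (1.76), Sdhd 8095 ± 187 against 2600 ± 1081 (1.74) and Uqcrc1 1252 ± 67.5 against 428 ± 78.3 (1.55). Cox7c, the member that fell, was at least 6.66-fold lower, on a probe set that measured only 226 ± 37.4 in reference RNA.

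Genes of dividing cells were lower in kidney. All 39 cell cycle genes fell, with a median log2 fold change of −4.02 (−3.81 at the bound; camera adjusted p = 5.96e-12). Bub1, a spindle checkpoint kinase gene, measured 19.3 ± 11.4 in kidney and 1376 ± 95.6 in reference RNA, at least 40.8-fold lower, and Bub1b was at least 23.2-fold lower. Kif23, a kinesin of cytokinesis, measured 14.8 ± 20.7 against 764 ± 37.7 (−4.29 at the bound), and Cdc20, an activator of the anaphase-promoting complex, 58.1 ± 7.35 against 2484 ± 1029 (−5.26). All 29 genes of fibroblasts and the extracellular matrix fell (median −2.57; camera adjusted p = 1.49e-10). Fn1, which encodes fibronectin, measured 410 ± 50.3 against 8556 ± 344 (−4.38), the collagen cross-linking enzyme gene Lox 426 ± 196 against 9146 ± 308 (−4.50), the collagen gene Col5a2 85.7 ± 11.8 against 2273 ± 153 (−4.67) and Fbln2 36.9 ± 31.0 against 610 ± 100 (−4.54).

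Of 15 myoblast and muscle genes, 12 fell and 1 rose, with a median log2 fold change of −1.84 (−0.85 at the bound; camera adjusted p = 0.0347). That call was lost with adjusted p = 0.248 with an estimated correlation, and without replicate 2 of the reference at 10 ng (adjusted p = 0.0576). Myf5, a regulator of muscle fate, measured 1.17 ± 0.404 against 1392 ± 99.6, at least 41.3-fold lower, and Myog was at least 2.97-fold lower. Mylpf, a myosin light chain gene, measured 48.1 ± 20.2 against 760 ± 73.5 (−3.94), and Actc1, the member that rose, 766 ± 81.9 against 61.7 ± 3.52 (3.55). Of 8 pluripotency genes measured, 4 fell and 1 rose (median −1.15, −0.51 at the bound; camera adjusted p = 0.5). Dppa2 was at least 36.2-fold lower, Klf4 measured 508 ± 67.0 against 1789 ± 336 (−1.80), Dppa4 47.3 ± 18.4 against 164 ± 24.9 (−1.76), and Esrrb was at least 18.9-fold higher in kidney.

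Markers of blood cells went both ways. T lymphocyte genes counted 3 higher and 6 lower of 11 (median log2 fold change −1.06, −0.80 at the bound; camera adjusted p = 0.181). Lat, a T cell receptor adaptor gene, measured 38.9 ± 17.3 in kidney against 750 ± 105 (−4.21), Thy1 103 ± 26.4 against 901 ± 111 (−3.10), Cd28 48.8 ± 21.4 against 343 ± 44.3 (−2.81) and Cd3d 572 ± 67.1 against 31.1 ± 22.7 (3.71 at the bound). The other genes that rose were Cd2 (1.15) and Cd8a (1.01), chosen for mention after their values were seen, as was Ly86 below. B lymphocyte genes counted 2 higher and 7 lower of 12 (median −0.61; camera adjusted p = 0.437). Ms4a1 measured 28.5 ± 27.3 against 828 ± 160 (−4.20 at the bound), Pou2af1 494 ± 205 against 5039 ± 561 (−3.43), Cd79b 129 ± 21.7 against 810 ± 144 (−2.61), while Ighm, the IgM heavy chain, measured 2309 ± 79.4 against 46.2 ± 16.0 (5.58) and Ly86 570 ± 50.5 against 252 ± 23.3 (1.16).

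Macrophage genes split evenly, with 8 higher and 8 lower of 20 (median log2 fold change 0.24; camera adjusted p = 0.5). The median turned to −0.05 with no filter on low signals and to −0.36 with a filter on the mean of all arrays. The complement genes C1qb, C1qc and C1qa rose, C1qb from 35.1 ± 13.3 in reference RNA to 7142 ± 414 in kidney (7.57), C1qc at least 24.0-fold and C1qa at least 7.65-fold. Clec4d measured 218 ± 9.02 in kidney against 3529 ± 183 (−3.99). Of 15 hepatocyte genes, 13 rose and 1 fell, with a median of 3.69 (3.01 at the bound; camera adjusted p = 2.47e-05). That call was lost with a filter on the mean of all arrays (adjusted p = 0.268). Ttr, which encodes transthyretin, measured 9682 ± 197 against 8.63 ± 1.37, at least 288-fold higher, and Apoc3 2611 ± 85.5 against 40.7 ± 5.51 (5.88). Fga was at least 38.1-fold and Serpina1b at least 26.5-fold higher, while Afp measured 40.1 ± 37.0 against 408 ± 27.2 (−3.97) and was chosen for mention after its value was seen.

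Of 23 genes of epithelial keratins and junctions, 13 rose and 6 fell, with a median log2 fold change of 1.31 (1.24 at the bound; camera adjusted p = 0.0285). That call was lost with adjusted p = 0.115 with an estimated correlation, with arrays centred on their medians (adjusted p = 0.072) and with all arrays in 1 fit (adjusted p = 0.0523). The claudin gene Cldn8 was at least 211-fold higher, Cdh16, the kidney cadherin, measured 4861 ± 211 against 43.1 ± 26.2 (6.83) and Cdh1, E-cadherin, 7174 ± 276 against 155 ± 45 (5.53). Pkp1, which encodes a desmosomal plakophilin, was at least 6.95-fold lower.

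Ribosomal protein genes were lower in kidney, with 36 of 43 called lower and 0 higher, a median log2 fold change of −0.57 and a camera adjusted p of 1.67e-06. With an estimated correlation the call was lost (adjusted p = 0.352 with an estimated correlation). Rps25 measured 628 ± 103 against 5867 ± 218 (−3.23), Rpl12 62.5 ± 30.3 against 548 ± 36.3 (−3.18), Rpl14 345 ± 21.6 against 1891 ± 73.0 (−2.44) and Rps27 211 ± 119 against 710 ± 251 (−1.85). Each of these lay below the list's median signal of 14410 in the reference at 10 ng, so their large falls do not stand for the list. Whether these probe sets report the main transcript was not tested. Heat shock and chaperone genes counted 3 higher and 10 lower of 23 (median −0.35; camera adjusted p = 0.126). Hspa1b measured 6497 ± 162 against 2144 ± 102 (1.60), Hspa1a 297 ± 173 against 33.3 ± 27.7 (2.51 at the bound), Hspb8 322 ± 64.7 against 1031 ± 75.7 (−1.68) and Cct8, of the cytosolic chaperonin, 1788 ± 127 against 4393 ± 302 (−1.30). Hspa4, the other gene that rose (0.74), was chosen for mention after its value was seen.

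Of 15 housekeeping genes, 1 rose and 10 fell, with a median log2 fold change of −0.42 (camera adjusted p = 0.0361). That call was lost with adjusted p = 0.352 with an estimated correlation, under quantile normalization (adjusted p = 0.0997), with arrays centred on their medians (0.143 adjusted), with a filter on the mean of all arrays (0.0887), and without kidney replicate 1, 2 or 3 (0.0776, 0.0603 and 0.0505). Gusb measured 271 ± 16.4 against 1230 ± 165 (−2.16), Tubb5 5439 ± 124 against 11424 ± 517 (−1.07), Ldha 6480 ± 166 against 12783 ± 1317 (−0.98), and Sdha, the member that rose, 7080 ± 222 against 2593 ± 62.9 (1.45). Replication-dependent histone genes, 7 of them measured, counted 2 higher and 2 lower, with a median of 0.16 and a mean of −0.09 (camera adjusted p = 0.56). H2aw measured 2007 ± 229 against 683 ± 70.9 (1.55), H1f2 11375 ± 117 against 5915 ± 791 (0.95), H1f4 48.9 ± 15 against 161 ± 9.60 (−1.68), and H3c4 was at least 1.04-fold lower.

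**Figure D1:**
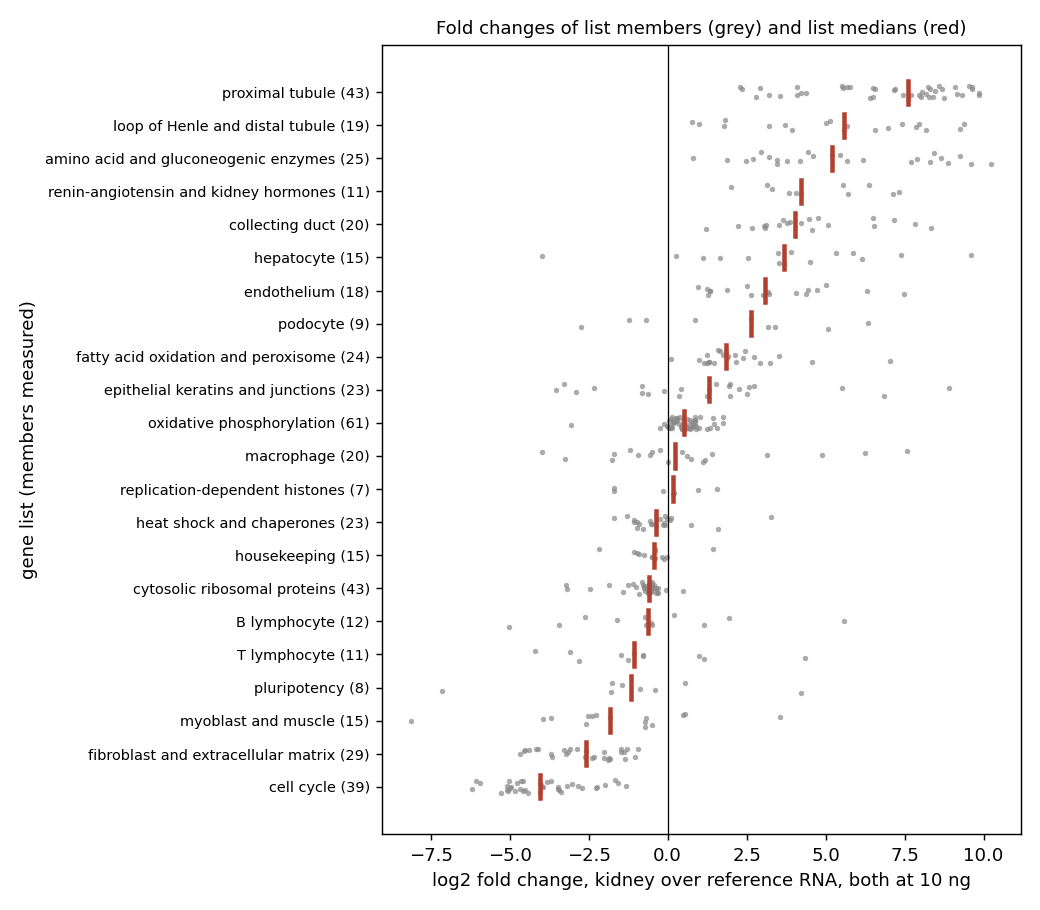
Log2 fold changes of kidney over reference RNA at 10 ng (x axis) for the members of 22 gene lists (y axis, number measured in brackets), each grey point 1 gene and each red mark the list's median. Proximal tubule genes lie farthest to the right (median 7.62) and cell cycle genes farthest to the left (median −4.02), and no list's median changed sign under either scaling alternative.

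Among the 12 genes with the largest fitted rise in kidney was Spink1, a secreted trypsin inhibitor gene (gene ID 20730, chromosome 18, 43728069 to 43737237 on GRCm38.p6). It measured 13108 ± 444 in kidney and 5.97 ± 7.93 in reference RNA, at least 389-fold higher (adjusted p = 4.83e-05, n = 3). The reference signal of all 12 lay below background, so each fold is a lower bound and their order is not known. Guca2b, which encodes uroguanylin, was at least 341-fold and Sult1d1, a sulfotransferase gene, at least 292-fold higher. Tmem229a was at least 199-fold, the glycosyltransferase gene Ugt3a2 at least 310-fold, the defensin gene Defb29 at least 223-fold, Ces1f, a carboxylesterase gene, at least 139-fold and Spp2 at least 232-fold higher. Hbb-b2, an adult beta globin gene of red blood cells, measured 8746 ± 110 against 5.60 ± 2.21, at least 260-fold higher. The probe set that stood for the alpha globin gene Hba-a1, looked up after the data were seen, lay below background in both (4.30 ± 2.7 and 11.4 ± 7). Probe sets naming several genes were not looked up, so this does not show that alpha globin was absent. The others of the 12 were Hao2, Slc27a2 and Slc13a1.

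Crabp1, which encodes a retinoic acid binding protein (gene ID 12903, chromosome 9, 54764748 to 54773110), was among the 12 genes with the largest fitted fall, 11 of which lay below background in kidney, so that their order is not known. It measured 11.8 ± 16.1 in kidney and 5400 ± 290 in reference RNA, at least 160-fold lower (adjusted p = 0.000202, n = 3). Rpl39l, a ribosomal protein paralogue, measured 23.3 ± 7.05 against 4599 ± 200 and was at least 137-fold lower, and Ereg, the growth factor epiregulin, 31.4 ± 23.1 against 4941 ± 302 (log2 fold change −6.80 at the bound). Pax3 was at least 38.0-fold, Hoxc13 at least 33.8-fold and Bnc1 at least 57.4-fold lower. Phex was at least 63.1-fold, Spinkl at least 50.1-fold, Elavl2 at least 31.5-fold and Dscc1, of sister chromatid cohesion, at least 28.2-fold lower, and the others were Myf5 and Dppa2.

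In all, limma called 16246 of 27022 probe sets between kidney and reference RNA at 10 ng (60.1%), 6201 higher and 10045 lower, at an adjusted p under 0.05. At least a 2-fold change was seen in 11807 of them. By gene, 8043 of 12820 were called, 3475 higher and 4568 lower. The 3 kidney arrays did not overlap the 3 reference arrays in 69.7% of probe sets, where chance gives 10%. Of 2997 genes with more than 1 called probe set, 245 had probe sets called in opposite directions. The higher share of the calls was 38.2%, and became 49.7% (7635 higher, 7739 lower) with each array centred on its median. The median log2 fold change of all probe sets was −0.34, and became −0.07 with centring and −0.19 with quantile normalization. All lists were fixed before the data were examined, and adjusted over the list alone the counts were the same except for podocyte genes (6 higher, 3 lower) and ribosomal protein genes (0 higher, 41 lower). Camera called 15 of the 22 lists, and the calls on 10 of them held with an estimated correlation, all but oxidative phosphorylation, myoblast and muscle, epithelial, ribosomal protein and housekeeping genes. The fry test, which asks only whether a list moves on balance in 1 direction, passed the threshold for 19 lists, all but histone, pluripotency and macrophage genes.

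The kidney profile was also set against less reference RNA, where tissue and input differ together. All 43 proximal tubule genes rose against the reference at 3 ng and at 0.3 ng (median log2 fold changes 7.42 and 7.18, or 6.35 and 6.44 at the background bound; camera adjusted p = 1.78e-20 and 1.99e-21). Of 19 loop of Henle and distal tubule genes, 16 rose against 3 ng and 17 against 0.3 ng, and of 20 collecting duct genes, 20 and 19, with 0 lower in each case. Cell cycle genes fell, 39 of 39 against 3 ng and 36 of 39 against 0.3 ng (medians −4.02 and −4.00, or −3.68 and −3.33 at the bound), as did 29 and 27 of 29 fibroblast and matrix genes (−2.35 and −2.53). Umod measured 18 ± 10.5 in the reference at 3 ng and 12.1 ± 8.64 at 0.3 ng, against 10850 ± 53.4 in kidney, and Fn1 8248 ± 248 and 9291 ± 462, against 410 ± 50.3 (log2 fold changes −4.33 and −4.50, n = 3). Adjusted over the list alone, the counts at 0.3 ng were 20 for collecting duct, 38 for cell cycle and 29 for fibroblast and matrix genes, and otherwise as given. Oxidative phosphorylation genes counted 40 higher and 1 lower of 61 against 3 ng (adjusted over the list alone, 41 and 1) and 17 higher and 0 lower against 0.3 ng (14 and 0), with adjusted p = 0.172 and 0.2 with an estimated correlation.

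Against the reference at 3 ng, 15308 probe sets were called, 5886 higher and 9422 lower (38.5% higher). With arrays centred on their medians the split was 7623 higher and 6452 lower (54.2% higher), and the median log2 fold change of all probe sets moved from −0.35 to 0.02. Against the reference at 0.3 ng, 9414 were called, 4904 higher and 4510 lower, with a median of −0.06 (−0.27 with centring). Without kidney replicate 1, 2 or 3 the last count was 5516, 5549 and 5529. Across probe sets, which are not independent, fold changes against 10 ng and against 3 ng correlated with r = 0.97 and a slope of 0.98, and 13469 probe sets were called in both, 5250 higher, 8218 lower and 1 in opposite directions (Zfp59, 1.67 against 10 ng and −0.58 against 3 ng, named after its value was seen). Fold changes against 10 ng and 0.3 ng correlated with r = 0.90 and a slope of 0.96, and 8355 were called in both, 4073 higher, 4234 lower and 48 opposite. The comparisons share the kidney arrays, so unchanged groups would give r = 0.52 and 0.34 in 20 simulations, and part of the excess may come from those arrays. The covariances were 3.85 and 3.79, against 0.0934 and 0.0940 simulated. Independent calls would overlap in 1351 higher and 3502 lower probe sets at 3 ng, and in 1125 and 1677 at 0.3 ng.

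Lowering the reference input from 10 to 3 ng changed no probe set past the threshold, in a comparison that asks how far the same RNA gives the same profile from less material. Limma called 0 of 27022, with 2736 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0506. Dao, of D-amino acid breakdown, measured 31.2 ± 3.35 at 3 ng and 4.60 ± 1.1 at 10 ng (n = 3), both under background, and Ndufv1, of respiratory complex I, 1178 ± 173 and 2482 ± 446 (log2 difference −1.07, adjusted p = 0.294). The cell cycle genes Top2a and Cdc6 measured 6631 ± 2372 and 283 ± 32.6 at 3 ng, and 4632 ± 423 and 412 ± 106 at 10 ng. No list was called, the smallest camera adjusted p being 0.068 for macrophage genes (median −0.28). Adjusted over the list alone, Dao was called higher and Cyp27b1, the vitamin D 1-alpha-hydroxylase gene, lower (8.43 ± 6.81 against 61.9 ± 29.1). The groups did not overlap in 17.7% of probe sets, where chance gives 10%, and the median log2 difference was −0.01. The count was 1 with arrays centred on their medians, 5 with all arrays in 1 fit and 37 with array weights. In simulated data of this size, 24% of probe sets with a 4-fold change and 0% with a 2-fold change were called. Each simulated probe set had the mean spread of others of like signal, so these shares are not the power for any single gene.

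At 0.3 ng, 215 probe sets differed from 10 ng, 206 of them lower. By gene, 70 were lower and 1 higher, of 12820. The gene that rose was Ddx11, which encodes a DNA helicase (gene ID 320209, chromosome 17, 66123513 to 66152174), from 293 ± 23.7 at 10 ng to 1983 ± 298 at 0.3 ng (log2 fold change 2.74, adjusted p = 0.0172, n = 3). Adgrl3, an adhesion G protein-coupled receptor gene (gene ID 319387, chromosome 5, 81019085 to 81827825), fell from 424 ± 150 to 2.20 ± 1.10, at least 12.1-fold lower, and Aplnr, the apelin receptor gene, was at least 12-fold lower. Gpm6a, a neuronal membrane glycoprotein gene, fell from 977 ± 149 to 35.8 ± 27.8 (−4.84). Apold1 was at least 9.99-fold, Lrp2bp at least 9.44-fold, the metalloproteinase gene Mmp23 at least 7.63-fold, Tusc1 at least 6.71-fold and Sntb1 at least 6.22-fold lower. Of the 206 probe sets called lower, 159 (77.2%) had a mean at 0.3 ng below background, and their median signal at 10 ng was 150, against 265 for all probe sets tested.

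No member of the 22 lists was called at 0.3 ng. Ribosomal protein genes had a median log2 difference of 0.31 and were called by camera relative to the other genes (adjusted p = 2.68e-10). That call was lost with adjusted p = 0.494 with an estimated correlation, and under quantile normalization, where the median was 0.02 (adjusted p = 0.723). Oxidative phosphorylation genes had a median of 0.08, a mean of −0.02 and a camera adjusted p of 0.0162, lost with adjusted p = 0.494 with an estimated correlation. Under quantile normalization their median turned to −0.04 (adjusted p = 0.832), and the call was lost with no filter (adjusted p = 0.149), without replicate 1 or 3 of the reference at 10 ng (0.0741 and 0.0667) and without replicate 1 or 3 at 0.3 ng (0.141 and 0.0622). Median and mean also differed in sign for endothelial, T lymphocyte, fibroblast and heat shock genes, none of them called. Uncalled examples were Hprt, at 1884 ± 127 against 3338 ± 293 (−0.82, adjusted p = 0.17), Cdh1, at 34.8 ± 16.8 against 155 ± 45 (−2.10, adjusted p = 0.107), and the collagen gene Col5a2, at 1134 ± 312 against 2273 ± 153 (−1.04, adjusted p = 0.177). Adjusted over the list alone, Cyp27b1, Pth1r and the proximal tubule gene Slc7a7 were called lower, and Ace higher (61.3 ± 14.6 against 22.9 ± 9.22).

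The median log2 difference of all probe sets between 0.3 and 10 ng was −0.23, and became 0.22 with centring and −0.07 with quantile normalization. With centring 80 probe sets were called, 12 higher and 68 lower (15% higher, against 4.19% of the 215). The count was 71 under quantile normalization, 76 with no filter, 61 with a filter on the mean of all arrays, 1571 with all arrays in 1 fit and 0 with the replicate number as a block. Raising signals under background to it, an alternative chosen after seeing the data, gave 555. Without replicate 1, 2 or 3 at 10 ng the count was 0, and without replicate 1 or 3 at 0.3 ng it was 595 and 569. The fit takes the same spread for both groups, though the median SD was 0.69 at 0.3 ng and 0.24 at 10 ng. Leaving out an array also makes the groups unequal in size, so these counts cannot show how far a particular array matters. The fit of all arrays takes the same spread for all 4 groups. At an unadjusted p under 0.05 there were 4175 probe sets, and the groups did not overlap in 25.7%, where chance gives 10%. The simulated data gave no call at 2-fold or 4-fold (0% of probe sets). They held no larger change, whereas Adgrl3 was at least 12.1-fold lower, so that share does not give the power for such falls. Differences at 3 and 0.3 ng against the same 10 ng arrays correlated with r = 0.25, where unchanged groups would give 0.24, with covariances of 0.118 and 0.0685 and 0 probe sets called in both.

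**Figure D2:**
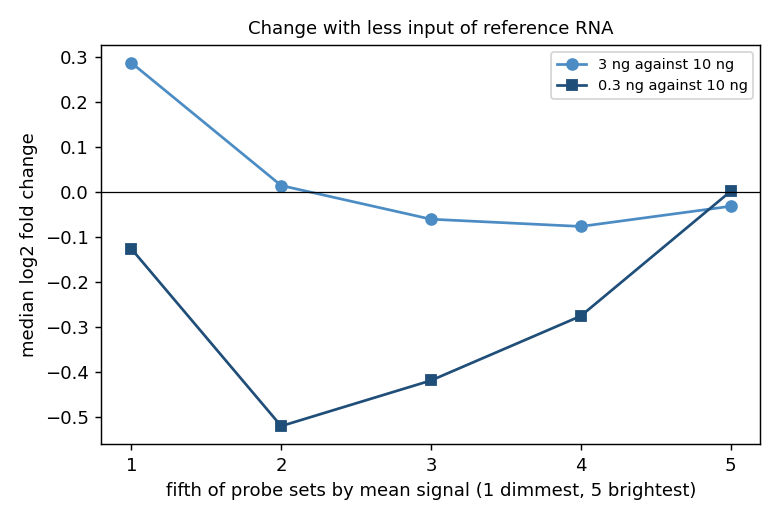
Median log2 fold change (y axis) of the reference at 3 ng and at 0.3 ng against 10 ng, for 5 equal groups of the probe sets (x axis, 1 dimmest). The groups were ordered by mean signal in the reference at 10 ng. That signal is the baseline of both fold changes, so the ordering can by itself raise the dimmest group. At 0.3 ng the medians were −0.13, −0.52, −0.42, −0.28 and 0.0011 from the dimmest to the brightest group.

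Against 3 ng, 65 probe sets differed at 0.3 ng, 63 lower and 2 higher. By gene, 21 fell, and 1 rose, again Ddx11 (from 231 ± 83.1 to 1983 ± 298, log2 fold change 3.12, adjusted p = 0.0464, n = 3). Epha4, an ephrin receptor gene, measured 22.3 ± 10.9 at 0.3 ng against 798 ± 51.7 at 3 ng, at least 23.7-fold lower, Adgrl3 was at least 11.8-fold, Lrp2bp at least 9.99-fold and Tusc1 at least 5.67-fold lower. Ccdc62 was at least 5.31-fold, Mmp23 at least 5.03-fold and Pdzd2 at least 4.17-fold lower, and Gpm6a fell by 4.77 on the log2 scale. Among the lists, camera called ribosomal protein (median 0.34, adjusted p = 3.18e-11), oxidative phosphorylation (0.12, adjusted p = 0.000129), housekeeping (0.20, adjusted p = 0.033) and fibroblast and matrix genes (0.11, adjusted p = 0.0411). None held, with adjusted p = 0.885, 0.836, 0.836 and 0.914 with an estimated correlation, and no member was called. Adjusted over the list alone, the hepatocyte gene Apoh was called lower (11.2 ± 6.52 against 49.7 ± 9.46). The count was 3 under quantile normalization, 21 with centring, 0 with no filter, 22 with a filter on the mean, 18 with an intensity trend, 1386 with all arrays in 1 fit, 147 with array weights and 0 with a replicate block. It was 0 without replicate 1, 2 or 3 at 3 ng and without replicate 1 or 2 at 0.3 ng, and 35 without replicate 3.

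A test of any difference among the 3 inputs over the 9 reference arrays called 529 probe sets (limma F-test, 4636 at an unadjusted p under 0.05). It called 168 under quantile normalization, 242 with centring, 318 with no filter, 266 with a filter on the mean, 823 with an intensity trend and 132 with a replicate block. Without replicate 1, 2 or 3 at 10 ng the count was 105, 125 and 106, at 3 ng 222, 210 and 185, and at 0.3 ng 1086, 856 and 1299. This test also takes the same spread for all inputs. With groups of unequal size these counts therefore cannot show how far a particular array matters.

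Replicate arrays of the reference spread most at 0.3 ng, in the comparison that asks how precision changes with input. The median SD of log2 signal among 3 arrays was 0.26 for kidney, 0.24 for the reference at 10 ng, 0.31 at 3 ng and 0.69 at 0.3 ng, or coefficients of variation of 18.1%, 17.1%, 21.8% and 47.7%. At 0.3 ng, 33.1% of probe sets had an SD over 1, against 4.63% at 10 ng. In the third of the probe sets with the lowest signal in the reference at 10 ng, the SD was 0.96 at 0.3 ng and 0.45 at 10 ng. In the third with the highest signal there it was 0.39 and 0.14. Single genes at 0.3 ng show the spread, such as the pluripotency gene Dppa2, at 800 ± 1336 against 1220 ± 89.7 at 10 ng, and Grhl2, an epithelial transcription factor gene, at 486 ± 754 against 2093 ± 309. Across probe sets, pairs of arrays correlated with r of 0.95 to 0.96 for kidney, 0.96 for the reference at 10 ng, 0.94 to 0.95 at 3 ng and 0.83 to 0.86 at 0.3 ng. Between groups r was 0.94 to 0.95 for 10 and 3 ng, 0.86 to 0.88 for 10 and 0.3 ng, and 0.64 to 0.65 for kidney and the reference at 10 ng.

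**Figure D3:**
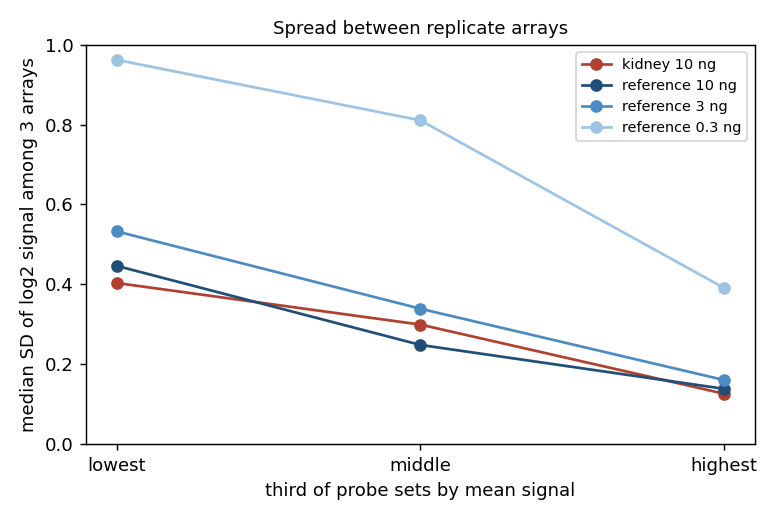
Median SD of log2 signal among the 3 arrays of each group (y axis) for the probe sets with the lowest, middle and highest mean signal (x axis, the 27022 tested in 3 equal groups). The reference at 0.3 ng lies above the other groups throughout, at 0.96, 0.81 and 0.39.

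Control probe sets at the ends of a transcript show how far an amplified product extends. For Gapdh, the log2 ratio of the 3′ to the 5′ probe set was 0.18 ± 0.0057 in kidney and 0.17 ± 0.031, 0.16 ± 0.032 and 0.21 ± 0.037 in the reference at 10, 3 and 0.3 ng (SD, n = 3). For Actb it was 2.42 ± 0.033 in kidney and 1.90 ± 0.064, 1.88 ± 0.087 and 1.95 ± 0.034 in the reference. The Actb ratio was 0.51 higher in kidney than in the reference at 10 ng (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow, and 0.24 adjusted over 12 tests). The ratio of Pcx, pyruvate carboxylase, was 3.80 ± 0.397 in kidney against 0.35 ± 1.14 (exact p = 0.1). Its 3′ probe set measured 1068 ± 87.6 in kidney and was far dimmer in the reference at 10 ng. Its 5′ probe set was dim in both, at 76.0 ± 27.7 and 69.6 ± 17.2. For Pcx, product length therefore cannot be told apart from the level of the transcript. Between inputs, Gapdh, Actb and Pcx had exact p between 0.2 and 0.9, and the small differences of Gapdh between kidney and reference and between 3 and 10 ng, and of Actb and Pcx between 3 and 10 ng, changed sign without single arrays (ranges −0.0089 to 0.022, −0.032 to 0.0025, −0.062 to 0.025 and −0.30 to 0.83). Under quantile normalization the Gapdh difference between 3 and 10 ng turned to 0.0080 and the Actb difference between 0.3 and 10 ng to −0.15. The Tfrc ratio was 3.19 ± 1.49 in kidney and 5.62 ± 1.12, 3.56 ± 0.439 and 2.07 ± 2.15 in the reference (exact p = 0.1 for each against 10 ng). Its 5′ probe set lay below background on 2, 3, 1 and 1 arrays.

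The middle probe set for 18S ribosomal RNA, the RNA of the small ribosomal subunit, measured 3931 ± 537 in the reference at 10 ng, 9496 ± 1560 at 3 ng, 12120 ± 312 at 0.3 ng and 7170 ± 1200 in kidney (SD, n = 3). The log2 differences from the reference at 10 ng were 1.27, 1.63 and 0.86 (two-sided exact permutation p = 0.1 each). The 5′ probe set differed by 1.86 at 3 ng and 2.45 at 0.3 ng, and the 3′ probe set by 0.69 and 0.75 (exact p = 0.1 each). In kidney these differed by 0.53 (332 ± 85.9 against 234 ± 88.2, exact p = 0.3) and 0.02 (148 ± 13.7 against 145 ± 10.4, exact p = 0.9). With the hybridization controls of each array subtracted, the middle, 5′ and 3′ probe sets differed by 1.28, 1.87 and 0.70 at 3 ng, by 1.26, 2.08 and 0.39 at 0.3 ng and by 1.13, 0.80 and 0.29 in kidney. The hybridization controls measured 7118 ± 390, 7070 ± 399, 9184 ± 407 and 5882 ± 45 in the same order.

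**Figure D4:**
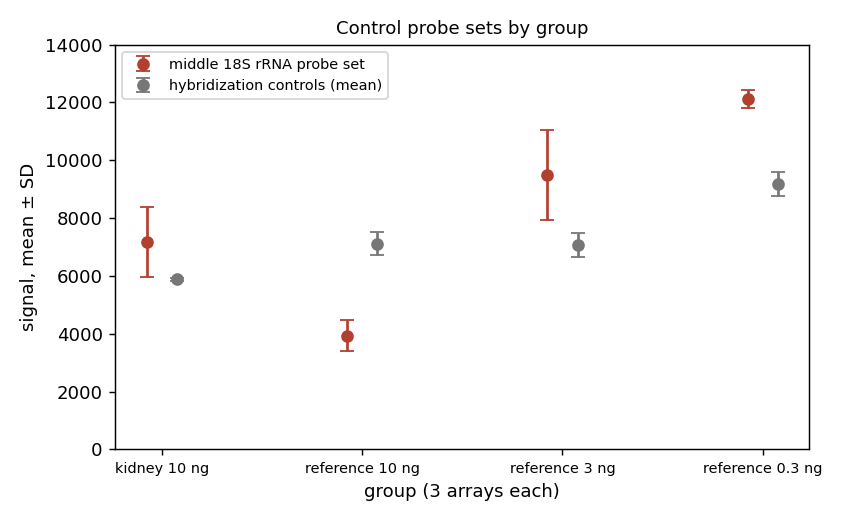
Signal (y axis, mean and SD of 3 arrays) of the middle 18S ribosomal RNA probe set and of the hybridization controls in each group (x axis). The 18S signal was 3931 in the reference at 10 ng and 12120 at 0.3 ng.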

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

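The tests of array scaling for the 18S signal, of scarce transcripts at 0.3 ng and of the brightest probe sets in kidney were chosen only after the result was seen.

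A signal in control probe sets outside the main measurement stood above the reference arrays at 10 ng, the middle 18S ribosomal RNA probe set measuring 7170 in kidney at 10 ng, 9496 in the reference at 3 ng and 12120 at 0.3 ng (means of 3 arrays), against 3931 in the reference at 10 ng. Scaling of the arrays is argued against as the whole cause, since the rise from 10 to 0.3 ng was still 1.26 on the log2 scale after the hybridization controls of each array were subtracted and that of the 5′ probe set 2.08, while that of the 3′ probe set went from 0.75 to 0.39, where scaling may account for a part. A rise of bright probe sets in general is argued against too, since that of 18S lay at percentile 100 of 3341 probe sets within a factor of 2 of its signal at 10 ng. What stays open is untested, and a candidate explanation is that ribosomal RNA gives a larger part of the amplified product when less RNA is put in. For the inputs the design gives no biological explanation, since the RNA is the same, and in kidney, where the middle, 5′ and 3′ probe sets differed by 1.13, 0.80 and 0.29 after the same subtraction (0.86, 0.53 and 0.02 before it), the tissue stays open as untested.

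Nearly all calls at 0.3 ng against 10 ng were lower signals, 206 of 215. Scaling of the arrays is argued against as the whole cause of that direction, since 87.3% of the calls were lower under quantile normalization and 85% with arrays centred on their medians. Loss of scarce transcripts may account for part of it, since 71.4% of the probe sets called lower lay below the median signal at 10 ng of all probe sets tested. No biological explanation was tested, since the RNA is the same. The 10 splits of the 6 arrays are too few for a share under 0.05, with 215 called in the real split and at most 0 in another.

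More probe sets were lower than higher in kidney at 10 ng, 10045 against 6201. Scaling of the arrays cannot be told apart from a difference between the tissue and the reference pool, since centring on array medians evens out the calls by itself (higher share 49.7%), as quantile normalization does in part (44.1%). The hybridization controls differed by −0.27 in kidney on the log2 scale (two-sided exact permutation p = 0.1). The median of all probe sets was −0.34, so scaling may account for a part of the shift. How many calls that part gives was not tested. The 100 brightest probe sets held 4.46% ± 0.0693 of the signal in kidney (SD, n = 3). In the reference at 10 ng the share was 5.34% ± 0.382, so it was not larger in kidney. The trimmed mean that sets the scale leaves out the brightest probe sets. This share therefore cannot decide whether a few genes taking most of the signal lowered the others. Scaling, a few genes taking most of the signal and the tissue all stay open, the tissue as untested. The 10 splits are too few for a share under 0.05, with 16246 called in the real split and at most 0 in another.

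For the other comparisons the 10 splits of 6 arrays are likewise too few for a share under 0.05. The real split called 0 at 3 ng against 10 ng (at most 0 in another), 65 at 0.3 ng against 3 ng (at most 0), 15308 for kidney against 3 ng (at most 0) and 9414 for kidney against 0.3 ng (at most 0). For any difference among the inputs, the real split of the 9 reference arrays, with 529 called, was the 1 of 100 with as many. The highest other split called 408. Chance is argued against, the share being under 0.05, but it is not excluded. The arrays at 0.3 ng spread more than those at 10 ng (median SD 0.69 against 0.24), so the splits are not fully alike.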

How the results depend on the processing

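The test with signals under background raised to it was chosen only after the results were seen. The counts for kidney against the reference at 10 ng (16246) and at 3 ng (15308) stayed within 1.5 times under every alternative run, at 11807 to 17075 and 11417 to 16296, as did the 15 lists called in kidney at 10 ng (12 to 16). Kidney against 0.3 ng (9414) ranged from 5516 to 10245 without single arrays. The 0 calls at 3 ng against 10 ng became 1 with centring, 5 with all arrays in 1 fit and 37 with array weights, and stayed at 0 without single arrays. The 215 calls at 0.3 ng against 10 ng became 71 under quantile normalization, 80 with centring, 76 with no filter, 61 with a filter on the mean, 555 with the floor, 1571 with all arrays in 1 fit and 0 with the replicate number as a block, and ranged from 0 to 595 without single arrays. The 65 calls at 0.3 ng against 3 ng became 3, 21, 0, 22, 1386 and 0 under quantile normalization, centring, no filter, the filter on the mean, all arrays in 1 fit and the block, 18 with an intensity trend and 147 with array weights, and ranged from 0 to 35 without single arrays. The 529 calls of any difference among inputs became 168, 242, 318, 266, 823 and 132 under quantile normalization, centring, no filter, the filter on the mean, the trend and the block, and ranged from 105 to 1299 without single arrays. The count of lists called at 3 ng (0) became 2 with centring, 1 with no filter and 2 with all arrays in 1 fit, and at 0.3 ng (2) became 0 under quantile normalization, 5 with centring and 1 with no filter, and ranged from 1 to 2 without single arrays. The median SD between replicates (kidney 0.26, reference 0.24, 0.31 and 0.69 at 10, 3 and 0.3 ng) was highest at 0.3 ng in every alternative run. It was 0.250, 0.321 and 0.657 under quantile normalization, 0.264, 0.317 and 0.724 with a smaller pseudocount and 0.235, 0.285 and 0.604 with a larger one for kidney and the reference at 3 and 0.3 ng. With no filter it was 0.394, 0.359, 0.429 and 0.762, and with the filter on the mean, which drops dim probe sets, 0.190, 0.185, 0.233 and 0.570. Without single arrays it ranged from 0.190 to 0.198 for kidney, 0.171 to 0.209 at 10 ng, 0.237 to 0.248 at 3 ng and 0.50 to 0.557 at 0.3 ng. An SD of 2 arrays has by itself a lower median than an SD of 3. These ranges can therefore be compared with each other but not with the values from 3 arrays. Agreement of kidney fold changes at 10 and 3 ng (r = 0.97) was 0.932 with no filter and 0.976 with the filter on the mean, and 0.961 to 0.969 without single arrays. At 10 and 0.3 ng (0.90) it was 0.912 with a larger pseudocount, 0.860 with no filter and 0.878 to 0.903 without single arrays, and between the inputs (0.25) 0.349 with no filter and 0.212 to 0.308 without single arrays. The macrophage median turned to −0.0505 with no filter and −0.359 with the filter on the mean, and the oxidative phosphorylation median at 0.3 ng to −0.0432 under quantile normalization. Without single arrays the Gapdh ratio ranged from −0.00889 to 0.0220 in kidney and −0.0317 to 0.00250 at 3 ng (0.00796 under quantile normalization), the Actb ratio from −0.0617 to 0.0254 at 3 ng (and −0.154 at 0.3 ng under quantile normalization), and the Pcx ratio from −0.304 to 0.831 at 3 ng. Of 107 genes named in kidney at 10 ng, at least 105 stayed called wherever they were all tested. Of 9 named at 0.3 ng against 10 ng, 0 stayed called with the block or without any of the 10 ng arrays. Apart from the filters and left-out arrays, which test fewer or more probe sets or fewer arrays, the cause was not tested. A left-out array also makes the groups unequal in size, in a fit that takes the same spread for them. Where the spread differs, as at 0.3 ng, counts without single arrays therefore cannot show how far a particular array matters. Replicate numbers do not pair the arrays, since residuals of arrays with the same number correlated by −0.0629 to 0.0159 and the own number was the closest in 11 of 36 cases. Signal over background limits what can be read in every group, with 41.2% of probe sets below it at 0.3 ng and 39.0% in kidney. In the reference at 10 and 3 ng the shares were 35.7% and 34.1%. The larger spread at 0.3 ng (median SD 0.69) is a further limit there.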

Other observations

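The tests of the gene families here and of the abundance of ribosomal protein transcripts were chosen only after the results were seen.

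Genes of antigen presentation and of families that include detoxification enzymes were mostly higher in kidney than in reference RNA at 10 ng. Of 17 genes of the major histocompatibility complex, 14 rose and 2 fell (median log2 fold change 2.24, or 1.77 with signals under background raised to it; camera adjusted p = 2.87e-05, and adjusted p = 0.0302 with an estimated correlation). The class II genes H2-Aa, H2-Ab1, H2-Ea and H2-Eb1 measured 8457 ± 148, 6600 ± 498, 2510 ± 53.3 and 5372 ± 14.6 in kidney, against 33.0 ± 4.26, 37.5 ± 19, 8.13 and 47.9 ± 29.5 in reference RNA (SD, n = 3). The class I genes H2-K1 and H2-D1 measured 9716 ± 210 against 4284 ± 372 (1.18) and 6818 ± 72.2 against 2102 ± 157 (1.70), and H2-Q2 was at least 14.4-fold higher. The classes were not tested against each other. Cytochrome P450 genes counted 21 higher and 5 lower of 31 (median 3.47, 2.94 at the bound) and glutathione S-transferases 15 higher and 2 lower of 20 (1.73). UDP-glycosyltransferases, taken by the symbol Ugt, counted 6 higher of 6 (7.68, 6.45 at the bound). The camera adjusted p of these families were 1.3e-05, 0.000139 and 5.05e-05, each with adjusted p = 0.0302 with an estimated correlation. The last family includes Ugt8a, so it is not of detoxification alone. Nor are the cytochrome P450 genes, also taken by symbol, which include the vitamin D genes Cyp24a1 and Cyp27b1 of the kidney hormone list. Cyp2e1 measured 7615 ± 191 in kidney and 13.2 in reference RNA (at least 226-fold higher), and Gsta2 8941 ± 439 and 116 ± 37.4 (6.27), while Mgst2 measured 49.6 ± 14.7 and 1547 ± 73.9 (−4.89). Sulfotransferases counted 4 higher of 5 (4.80, 4.41 at the bound; camera adjusted p = 0.00365) and subunits of the vacuolar proton pump 10 higher and 1 lower of 17 (0.90; camera adjusted p = 0.000452), lost with adjusted p = 0.0772 and 0.153 with an estimated correlation.

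Splicing factor genes were lower in kidney, with 1 higher and 35 lower of 46 (median −0.79; camera adjusted p = 1.3e-05, and adjusted p = 0.0302 with an estimated correlation). Aminoacyl-tRNA synthetases counted 0 higher and 14 lower of 16 (−0.97; camera adjusted p = 0.000256, lost with adjusted p = 0.133 with an estimated correlation). Hox genes went both ways. Hoxd10 measured 3479 ± 181 in kidney against 49.8 ± 22.7 in reference RNA (6.13), and Hoxd9 7890 ± 46.4 against 2155 ± 57.4 (1.87), while Hoxc8 measured 127 ± 36.6 against 569 ± 83.3 (−2.16) and Hoxc4 212 ± 29.3 against 942 ± 9.20 (−2.14). Of 26 Hox genes, 13 rose and 6 fell (camera adjusted p = 0.0465, lost with adjusted p = 0.133 with an estimated correlation). Imprinted growth genes counted 1 higher and 7 lower of 11 (camera adjusted p = 0.111), with Dlk1 at 16.8 ± 10.1 against 1954 ± 302 (at least 57.6-fold lower), Peg10 at 58.6 ± 17.0 against 733 ± 95.1 (−3.59) and Peg3 at 1511 ± 265 against 556 ± 62.6 (1.43). Not called were mitochondrial ribosome genes (20 higher, 10 lower of 76, camera adjusted p = 0.0689), interferon-stimulated genes (6 higher, 4 lower of 17, camera adjusted p = 0.298) and proteasome genes (4 higher, 7 lower of 47, camera adjusted p = 0.531). The proteasome median of −0.14 turned to 0.11 with arrays centred on their medians. That list was drawn up by symbol and also held Psmc3ip and Psme3ip1, genes of interacting proteins.

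Both Xist, the RNA of the inactive X chromosome, and genes of the Y chromosome gave signals in both RNAs. Xist measured 5632 ± 83.1 in kidney and 7436 ± 1250 in the reference at 10 ng, Eif2s3y 1089 ± 205 and 824 ± 126, and Kdm5d 669 ± 338 and 1083 ± 336 (SD, n = 3). At 0.3 ng the reference gave 348 ± 154 for Eif2s3y, 61.2 ± 43.2 for Kdm5d and 946 ± 808 for Uty, which measured 344 ± 23.5 in the reference and 209 ± 36.3 in kidney at 10 ng. Kap, the kidney androgen-regulated protein gene, measured 12800 ± 356 in kidney against 32.8 ± 8.29. Ptprc, the common leukocyte antigen, measured 677 ± 76.0 in kidney and 1853 ± 130 in the reference, and Alb, albumin, 136 ± 30.5 and 44.0 ± 26.6.

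Ribosomal protein genes stood 0.31 higher on the log2 scale at 0.3 ng than at 10 ng by their median. A candidate explanation is their abundance, with a median signal of 14410 at 10 ng. The list's median lay at percentile 26.4 of 10000 random lists of 43 genes matched on signal at 10 ng, whose own median was 0.32 (central 95% from 0.28 to 0.35), so the values that abundance needs are there. Nothing specific to ribosomal protein transcripts was needed to give that median in this test, which was found and run on the same data.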
